A study of Mus musculus with 6 samples.

How the data were processed

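RNA of the pyloric region of 6 mouse embryos at E18.5 was measured on CodeLink Mouse Whole Genome arrays, a one-colour platform read from biotin-labelled cRNA. Per the labels' protocols, embryos came from crosses of mice heterozygous for a Cre allele of Bapx1, were genotyped from yolk sac DNA, and gave total RNA by a column kit. The labels name 3 embryos as knockout and 3 as wildtype, and the series design calls the latter littermates. Each animal code in the labels begins with digits shared by 1 knockout and 1 wildtype embryo. These digits were taken as the litter, and the pairs were numbered 1 to 3.

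Per the file headers, the authors' scanner files were exported from the CodeLink Expression Analysis software and hold the spot mean intensity and the median intensity of the local background of each spot, neither of them normalized. The per-sample normalized values are intensity after background subtraction divided by the array's median, a median normalization that the authors' expression reports state for pair 1. The series' deposited value table holds intensity on the same linear scale. Its column medians lay between 0.997 and 1.02, and 93.5% to 97.0% of its probes lay within 1% of the scanner files' normalized values on the same array. No genome build, aligner or further step is given in the sources used here. Per the files, pair 1 was scanned and exported apart from pairs 2 and 3, which share a scan batch. These are called batch A and batch B.

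Each array held 36227 spots, of which 34967 were gene probes. The rest were 640 fiducial, 320 negative and 300 positive control spots, left out after background correction. Probe names came from the platform annotation, with symbols updated by gene ID for 21487 probes through a RefSeq gene table of assembly GRCm38.p6, kept as given for 128 and matched by RefSeq accession for 499. In all 22114 probes had 1 gene symbol, 681 had several and 12172 are unnamed here. Named probes covered 18507 symbols. No probe with several symbols was named. The array files name no build, so no coordinates are printed.

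Spot means were corrected with limma's normexp method (offset 50) against the local background median, quantile normalized over gene probes and taken to log2. Spots flagged masked, irregular or contaminated, 0.418% to 3.34% of gene probes on an array, were set missing, and saturated or dim spots stayed. A probe was tested if it was not flagged near background on at least 3 of the 6 arrays and had a value on at least 2 arrays of each group. This left 30207 probes and 16764 genes, each represented by the probe of the highest mean signal. The median spot signal above background was 204 and 207 in pair 1 and 109 to 131 in pairs 2 and 3, against local backgrounds of 38 to 46. Of 95 named genes 8 had more than 1 tested probe, and in 2 of them, Xaf1 and Wt1, the probes differed in sign.

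Groups were compared with limma (version 3.58.1, R 4.3.3; lmFit and eBayes without a block) with Benjamini-Hochberg adjustment at 0.05. The 27 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 over the 15667 genes with values on all 6 arrays, with camera at an estimated correlation and the fry directional test beside it. Lists under 5 genes were not tested, which left 26. With the preset correlation camera called 5 lists, 2 higher and 3 lower, and with an estimated correlation or fry 0. The estimated correlations of these 5 lists lay between 0.128 and 0.626, all above the preset. The list tests with blocks, within batch B, with array weights or with arrays left out used the preset alone. The design, the lists, the rule for named genes and the alternatives, except gene by gene array weights, were fixed before the data were examined. That rule names Nkx3-2; the 12 genes per direction with the largest change among those past the threshold with the same sign in all pairs, places left over going to the genes of smallest unadjusted p with an absolute log2 difference of at least 1, or 0.585 where too few; and the 3 members of each list with the largest moderated t-statistic. Some genes that the rule names are not reported here. As no gene passed, all 24 places were filled by p. Only 8 higher genes reached 1, and the wording then allows 2 readings: to keep those 8 and fill 4 places from 0.585 up, or to apply 0.585 to all 12. The first was tried, and the second was adopted after the genes had been seen; the results give both sets. Other genes, named as examples of a list or of a tissue, were chosen after their values were seen. Sex genes were left out of the ranked genes. A gene near background in all arrays of a group would have been given as a bound, and no gene named above needed one.

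The pairing was checked by correlating, across genes, the deviations of paired arrays from their group means. The correlations were 0.784, 0.409 and 0.576 for pairs 1, 2 and 3, all over 0.1, so the pairs were taken to pair the samples. Much of this followed the scan batch. Arrays of a batch correlated at 0.978 or more and arrays of different batches at 0.926 to 0.947, the first principal component held 72.1% of the variance, and by these deviations only 3 of the 6 arrays correlated best with their own partner among the arrays of the other group. Within batch B the difference of pair 2 from pair 3 correlated at -0.162 between the groups. The values therefore do not bear out the matching of pairs 2 and 3, which rests on the animal codes. No arrays of a group were duplicates, since their log2 values differed with an SD of at least 0.288.

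The gene and list tests were tested on simulated data with this design, 15667 genes and noise from the real fit without a batch. Of 100 genes changed by 1 log2 unit 38% were recovered, and of 100 changed by 2 units 93%, with 1 false call. All 10 lists shifted by 0.5 were called and 0 of 50 unshifted ones. With the litter pair as a block 96% and 100% were recovered, with 19 false calls, and 10 of 10 shifted and 1 of 50 unshifted lists were called. The simulated noise was drawn independently for each gene, so the members of a list did not vary together. These list counts therefore do not give the rate of false calls for lists whose members do, as those of the called lists did. The shares of genes recovered hold for such noise, without batch or litter effects, and are not the power on the real arrays. In the real data St8sia6 differed by -1.09 (SE 0.13) with the litter pair as a block and was not called. A count of 0 genes therefore does not show that changes of 1 log2 unit are absent. Alternatives covered the litter pair or the scan batch as a block, normexp with offset 10, subtraction with a floor, no background subtraction, median scaling, cyclic loess, the authors' normalized values, filters, flags, probe summaries, array weights, a robust trended prior, and leaving out arrays or pairs.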

Results

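Gene expression was measured in the pyloric region of mouse embryos labelled knockout for Nkx3-2 (also called Bapx1), a homeodomain transcription factor of the gut and skeletal mesenchyme, and of littermates labelled wildtype. The tissue was taken at E18.5, late in gestation, and comprised the distal stomach with a margin of gut on either side of the pyloric narrowing, so that each piece held stomach wall and the start of the intestine. Total RNA of 3 embryos labelled knockout and 3 labelled wildtype was hybridised to 6 one-colour CodeLink mouse arrays, 1 embryo per array. Each array labelled knockout shared the leading digits of its animal code with 1 array labelled wildtype, which gave 3 litter pairs. Pair 1 was scanned in batch A and pairs 2 and 3 in batch B. Between 13.2% and 16.7% of the gene probes were flagged near background on an array, and 55 to 145 were saturated. The number of arrays limits the precision of every value below, which are log2 normalized intensities.

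The targeted gene was read first, because it bears on the labels. Nkx3-2 was detected on all 6 arrays and read 7.85 ± 0.16 in the arrays labelled knockout and 7.74 ± 0.26 in those labelled wildtype (SD, n = 3 each). The log2 difference was 0.11 (SE 0.19, limma adjusted p = 1), with 0.26 in pair 1, 0.27 in pair 2 and -0.20 in pair 3. With scan batch as a block it was 0.11 (SE 0.12), and within batch B it was 0.03. The transcript was therefore not lower in the arrays labelled knockout. Where the probe lies relative to the altered part of the gene is not given in the sources used here, and a probe outside that part checks nothing. Directions below rest on the labels alone, so the groups are called by their labels.

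The question was which genes differ in the pyloric region when Nkx3-2 is missing. No gene passed the test across all genes. Tff2, Muc6 and St8sia6, examples from the 12 lower genes named below, were lower in the arrays labelled knockout in all 3 pairs. They are not the first 3 by p or by size. Gm11525 and 3110021A11Rik had a smaller unadjusted p than Muc6 and St8sia6, and Tnnc2 differed more than all 3. One sign in all 3 pairs is common: 3609 of 15667 genes had it, 1810 lower and 1799 higher, where independent signs would give 25%. Tff2, a trefoil peptide of mucous neck and antral gland cells, read 12.92 ± 0.36 against 14.41 ± 0.31 in the arrays labelled wildtype (SD, n = 3 each), a log2 difference of -1.49 (SE 0.25). Muc6, the mucin of the same gland cells, differed by -1.54 (SE 0.67), at 10.54 ± 1.20 against 12.09 ± 0.87. St8sia6, a sialyltransferase, differed by -1.09 (SE 0.40), and by -0.54 at its other tested probe, of lower signal.

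In limma, 0 of 16764 genes had an adjusted p under 0.05, and 0 had one under 0.1. At an unadjusted p under 0.05 there were 189 genes, 146 higher and 43 lower in the arrays labelled knockout. Chance alone would give 838 in a fit that accounts for the structure of the arrays. This fit has no block, so scan batch widens its residual spread. The lower count therefore does not show that the groups are alike. With the litter pair as a block 0 genes passed and 760 had an unadjusted p under 0.05, below 838. With scan batch as a block the counts were 0 and 978, the latter above 838, and the lowest adjusted p was 0.458. Genes vary together on these arrays, so neither distance from 838 shows how many genes differ. Within batch B, 2 arrays against 2, the counts were 0 and 1918 of 15943 genes. Batch A holds 1 array of each group and allows no test. Among 10515 probes that name no gene or several, 0 passed and 44 had an unadjusted p under 0.05. One setting ended the count of 0: limma array weights called 677 genes, 462 higher and 215 lower. That fit gave weights from 0.166 for wildtype replicate 1 to 6.96 for wildtype replicate 3 and stopped before it converged, while weights from the gene by gene method called 0.

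The 12 genes named as higher, by smallest unadjusted p among those with the same sign in all pairs, had log2 differences between 0.71 and 0.98. Car5a, a mitochondrial carbonic anhydrase, read 7.28 ± 0.25 against 6.30 ± 0.06 (SD, n = 3 each), a difference of 0.98 (SE 0.18). Tmem252 differed by 0.95 (SE 0.18) and Serpina1e, a serine protease inhibitor of the alpha-1 antitrypsin family, by 0.77 (SE 0.16). Asah2, the neutral ceramidase of the intestinal brush border, differed by 0.71 (SE 0.19), and Slc51b, a subunit of the basolateral bile acid transporter of the ileum, by 0.75 (SE 0.20). Hsd3b3, a steroid dehydrogenase, differed by 0.76 (SE 0.20), and Vwf, the von Willebrand factor of endothelium, by 0.78 (SE 0.20). The others were Nat8 at 0.81, Lrmda at 0.82, Snx20 at 0.73, Slc25a43 at 0.74 and Tmem144 at 0.89. Each of these 12 had an adjusted p of 1, and each was among the 677 genes called with the default array weights (adjusted p from 0.0106 to 0.0145). The rule for these places allowed 2 readings, and the one used was settled after the values were seen. Under the other reading 4 of the 12 higher genes stay (Car5a, Tmem252, Serpina1e and Nat8) and 8 are replaced by genes that reach a log2 difference of 1 with a larger p. Those are Bst1 at 1.22 (SE 0.41), the neurotensin gene Nts at 1.22 (SE 0.46), Rab30 at 1.00 (SE 0.42), Xlr4b at 1.04 (SE 0.51), the sterol transporter gene Abcg5 at 1.34 (SE 0.69), Zg16 at 1.78 (SE 1.21), Afp at 1.16 (SE 0.85) and Apoa2 at 1.13 (SE 0.89). Several of these rest on some pairs more than others: in pairs 1, 2 and 3 Afp differed by 2.65, 0.72 and 0.11, Apoa2 by 2.91, 0.09 and 0.39, Xlr4b by 0.28, 0.16 and 2.69, Abcg5 by 0.15, 2.15 and 1.74, and Rab30 by 0.08, 1.71 and 1.22. All 12 lower genes are named under both readings.

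The 12 genes named as lower had log2 differences between -1.79 and -1.02 and adjusted p of 1. Besides Tff2, Muc6 and St8sia6 they were Gm11525 at -1.12 and 3110021A11Rik at -1.10, whose function is not described here, Xaf1 at -1.37, and 6 genes of striated muscle. Those were the troponin gene Tnnc2 at -1.79 (SE 0.88), the fast myosin light chain gene Mylpf at -1.54 (SE 0.71), the myosin-binding protein gene Mybpc1 at -1.55 (SE 0.70), the perinatal myosin gene Myh8 at -1.28 (SE 0.77), the skeletal actin gene Acta1 at -1.18 (SE 0.63) and Myoz2 at -1.02 (SE 0.61). The Xaf1 value rested on knockout replicate 1, at 7.53 where the other 5 arrays lay between 10.96 and 11.42, and the other tested probes of Xaf1 differed by 0.08 and 0.04. Those of Mybpc1 differed by -0.48 and -1.33. 3110021A11Rik was near background on 2 arrays, knockout replicates 2 and 3, at 5.78 and 5.93. The size of its difference is therefore uncertain. Myoz2 here and Lrmda above were near background on 1 array each. Among the lower genes the default array weights called Tff2, Gm11525, 3110021A11Rik, St8sia6, Muc6 and Mybpc1, and among all named genes 36. Of 92 named genes with a value within batch B, 30 changed there by over 1.5 times or in sign, 4 of them in sign.

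**Figure D1:**
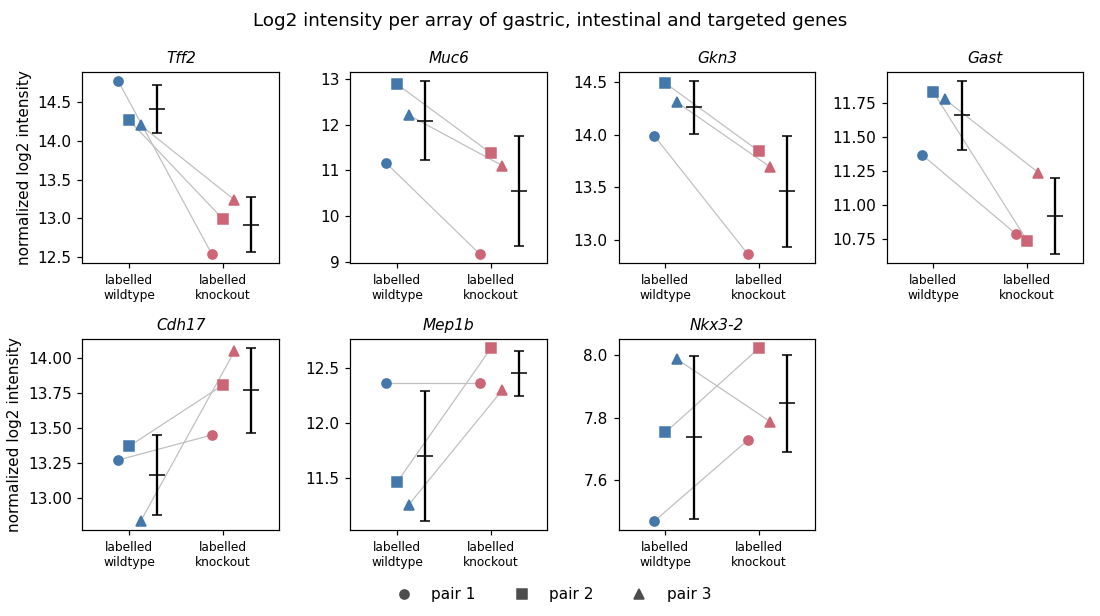
Normalized log2 intensity (y axis) of 7 genes on each array, by group label (x axis); circles, squares and triangles are pairs 1, 2 and 3, grey lines join the arrays of a pair, and bars give the mean ± SD of 3 arrays. Tff2, Muc6, Gkn3 and Gast were lower in the array labelled knockout in all 3 pairs, while Mep1b was higher in pairs 2 and 3 and differed by -0.01 in pair 1.

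The list of gastric surface, neck and antral epithelium was lower as a set in the arrays labelled knockout (camera adjusted p = 0.0082). It was not called with an estimated correlation (adjusted p = 0.547 with an estimated correlation). Its 3 leading members were Tff2, Muc6 and Gkn3, a gastrokine of the gastric glands, which differed by -0.80 (SE 0.29), at 13.46 ± 0.53 against 14.26 ± 0.25 (SD, n = 3 each). All 3 were lower in each of the 3 pairs, which the rule for naming Tff2 and Muc6 required, from -2.23 for Tff2 in pair 1 to -0.61 for Gkn3 in pair 3. The median over the 16 tested members was -0.07, with 10 lower and 6 higher, and the mean -0.30. The medians of pairs 1, 2 and 3 were 0.01, 0.05 and -0.51. The surface mucin gene Muc5ac differed by 0.00, Ctse by -0.06 and Gkn1 by 0.12, while Tff1 and Gkn2 were saturated in a group. Other members were lower with wide errors, namely Muc1 at -0.42 (SE 0.40), Pgc at -0.43 (SE 0.78) and Vsig1 at -0.29 (SE 0.40). Muc1 was lower in all 3 pairs and had an adjusted p = 0.0502 over the list alone with the litter pair as a block. Over all genes 0 members passed, and adjusted over the list alone 1 did (Tff2, adjusted p = 0.00973). With the litter pair as a block, 3 passed adjusted over the list alone, namely Tff2 (adjusted p = 0.00996), Muc6 (adjusted p = 0.00368) and Gkn3 (adjusted p = 0.00996). The list median was -0.06 with scan batch as a block (adjusted p = 0.00642), -0.16 within batch B (adjusted p = 0.00592) and 0.01 in pair 1, the only pair of batch A. The call was lost without knockout replicate 1 (adjusted p = 0.473), wildtype replicate 2 (0.161), wildtype replicate 3 (0.27) or pair 3 (0.0868). Its median was above 0 with median scaling (0.0121), the authors' per-sample intensities (0.03) and the series matrix values (0.0331), -0.34 and -0.19 with the default and the gene by gene array weights, and -0.36 to 0.03 over left-out arrays or pairs.

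The list of gastrointestinal endocrine cells had a median difference of -0.03 over 16 genes (camera adjusted p = 0.769), with 2 genes at an unadjusted p under 0.05. Gast, the gastrin gene of antral G cells, differed by -0.74 (SE 0.21), at 10.92 ± 0.28 against 11.66 ± 0.25 (SD, n = 3 each), and was lower in all 3 pairs. Gip and Cck, hormone genes of the upper intestine, differed by 0.41 (SE 0.15) and 0.41 (SE 0.18) and were higher in all 3 pairs. No member passed over all genes or adjusted over the list alone.

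The intestinal epithelium list was higher as a set in the arrays labelled knockout (camera adjusted p = 5.25e-09), with a median difference of 0.33 and 18 of 22 tested members higher. It was not called with an estimated correlation (adjusted p = 0.444 with an estimated correlation). Mep1b, the meprin beta gene of the brush border, read 12.45 ± 0.20 against 11.70 ± 0.59 (SD, n = 3 each), a difference of 0.75 (SE 0.31). Cdh17, the liver-intestine cadherin, differed by 0.61 (SE 0.23). Over all genes 0 members passed, and 0 did adjusted over the list alone. The higher values lay in batch B, where the median was 0.71 (adjusted p = 7.61e-13), with 0.54 in pair 2 and 0.58 in pair 3. In pair 1, the only pair of batch A, it was -0.16. With scan batch as a block the median was 0.33 (adjusted p = 3.62e-06). The median moved with single arrays, from 0.19 without wildtype replicate 2 to 0.58 without wildtype replicate 1, and was 0.17 without pair 3 and 0.57 and 0.65 with the default and the gene by gene array weights. The goblet cell genes Muc2 and Tff3 differed by -0.01 and -0.23. In the same pairs the mesenchymal lists differed the other way. The medians of the stomach and pyloric mesenchyme regulators were 0.11, -0.24 and -0.21 in pairs 1, 2 and 3, those of visceral smooth muscle 0.11, -0.19 and -0.20, and those of the extracellular matrix 0.11, -0.22 and -0.21.

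The skeletal muscle list was lower as a set in the arrays labelled knockout (camera adjusted p = 1.67e-06), with a median difference of -0.74 and 10 of 11 members lower. It was not called with an estimated correlation (adjusted p = 0.444 with an estimated correlation). Mylpf read 10.03 ± 1.33 against 11.57 ± 0.84 and Tnnc2 8.37 ± 1.64 against 10.16 ± 1.09 (SD, n = 3 each), so the arrays within a group differed widely. The centred list score ran from -0.77 in knockout replicate 2 to 1.44 in wildtype replicate 3. Whether the pieces differed in their content of striated muscle was not tested, so the difference cannot be assigned to the pyloric wall or to the genotype. The array labelled knockout was the lower in each pair, with medians of -0.15, -1.09 and -0.96. Over all genes 0 members passed and 0 did adjusted over the list alone, where 8 did with the litter pair as a block. The median was -0.74 with scan batch as a block (adjusted p = 0.000581) and -1.05 within batch B (adjusted p = 0.00122). It was -0.25 without wildtype replicate 3, -1.13 without knockout replicate 3, -1.18 without wildtype replicate 1 and -1.31 with array weights.

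The cell cycle list was lower as a set (camera adjusted p = 0.0187), by a median of -0.13, with 16 of 20 members lower. It was not called with an estimated correlation (adjusted p = 0.444 with an estimated correlation). Cdk1, the mitotic kinase gene, differed by -0.25 (SE 0.17), Pcna by -0.22 (SE 0.15) and Top2a by -0.21 (SE 0.19), and 0 members passed over all genes or adjusted over the list alone. The median was -0.13 with scan batch as a block (adjusted p = 0.0376) and -0.17 within batch B (adjusted p = 0.0538). In pairs 1, 2 and 3 the medians were -0.05, 0.09 and -0.26, so pair 2 went the other way. Of the 20 members 3 were lower in all 3 pairs and 1 was higher in all 3. The call was lost without wildtype replicate 1 (adjusted p = 0.478), knockout replicate 2 (0.368), knockout replicate 3 (0.155), wildtype replicate 3 (0.104), pair 1 (0.0538) or pair 3 (0.396). The median ran from -0.23 to -0.04 over left-out arrays or pairs and was -0.26 with array weights and -0.07 with median scaling.

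The liver list was higher as a set (camera adjusted p = 0.0209), by a median of 0.50 over 10 genes, all with positive differences. It was not called with an estimated correlation (adjusted p = 0.572 with an estimated correlation). This value came from 1 array. The list differed by 2.57 in pair 1, where Afp read 11.99 in knockout replicate 1 and 9.34 in wildtype replicate 1, Fgg 9.36 and 6.81, and Fga 9.69 and 7.12. In pairs 2 and 3 it differed by -0.31 and -0.45, and within batch B the list was lower, by a median of -0.38 (adjusted p = 0.0269). With scan batch as a block the median was 0.50 (adjusted p = 0.0376). Without knockout replicate 1 the list median was -0.21, in the lower direction (adjusted p = 0.00158). The call was also lost without wildtype replicate 1 (adjusted p = 0.271) or wildtype replicate 2 (0.102). Over all genes 0 members passed, and 0 did adjusted over the list alone.

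**Figure D2:**
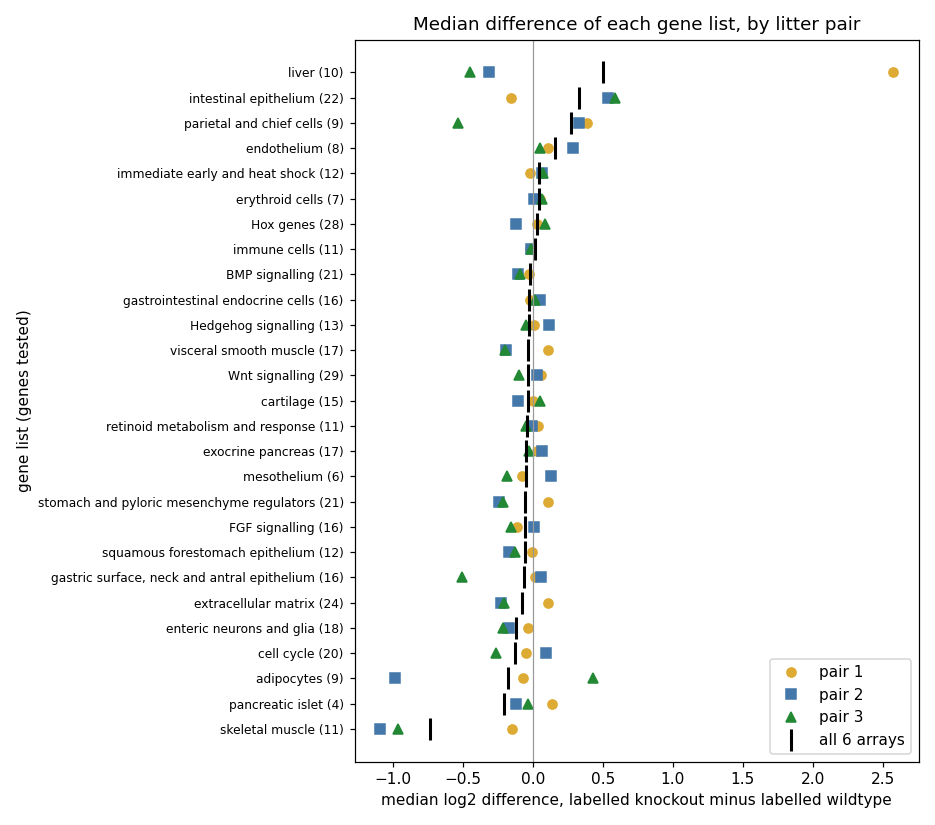
Median log2 difference, arrays labelled knockout minus arrays labelled wildtype (x axis), of each gene list (y axis, number of tested genes in brackets); circles, squares and triangles are pairs 1, 2 and 3 and black bars are the median of the fit on all 6 arrays. The intestinal list lay at 0.54 and 0.58 in pairs 2 and 3 and at -0.16 in pair 1, skeletal muscle lay below 0 in all 3 pairs, and the liver list reached 2.57 in pair 1 alone.

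With all 6 arrays camera called none of the other 21 tested lists, and for none of them did a member pass over all genes or adjusted over the list alone. The stomach and pyloric mesenchyme regulators had a median difference of -0.05 (adjusted p = 0.0914), with Gata3 at -0.42 (SE 0.17), the BMP receptor gene Bmpr1b at -0.61 (SE 0.33) and the BMP antagonist gene Grem1 at -0.30 (SE 0.17). Bmpr1b had no value in knockout replicate 1, so scan batch enters its difference, and with scan batch as a block it was -0.32 (SE 0.17). Visceral smooth muscle had a median of -0.03 (adjusted p = 0.195), with Cnn1 at -0.22, Synpo2 at -0.15 and Mylk at -0.26. Enteric neurons and glia had -0.12 (adjusted p = 0.0799), with 15 of 18 members lower, among them the neuropeptide genes Vip at -0.76 (SE 0.40) and Gal at -0.46 (SE 0.25), and Uchl1 at -0.24. Vip lacked the same array and was -0.38 (SE 0.15) with scan batch as a block. The squamous forestomach list had -0.06 (adjusted p = 0.0799), with Krt5 at -0.32, Sprr3 at -0.34 and Krt13 at -0.51. Parietal and chief cells had 0.27 (adjusted p = 0.395), with Hdc at 0.46, Chia1 at 0.29 and Kcnq1 at -0.17.

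Signalling lists stayed near 0. The Hox genes had a median of 0.03 and a mean of -0.02 (adjusted p = 0.812), with Hoxa6 at -0.42, Hoxd8 at 0.18 and Hoxb8 at -0.18. Wnt signalling had -0.04 (adjusted p = 0.651), with Sfrp1 at -0.27, Fzd4 at -0.24 and Dkk3 at -0.29. Hedgehog signalling had a median of -0.03 and a mean of 0.01 (adjusted p = 0.803), with Shh at -0.26, Sufu at 0.22 and Gli1 at 0.23. Fzd4 and Gli1 had no value in wildtype replicate 1, and with scan batch as a block they were -0.16 and 0.12. Hoxa6 was near background on 3 arrays and Shh on 2, so the sizes of their differences are uncertain. BMP signalling had -0.02 (adjusted p = 0.395), and Bmpr1b and Grem1 were among its leading members. FGF signalling had -0.05 (adjusted p = 0.195), with Fgf1 at 0.30, Spry4 at -0.21 and Spry1 at -0.45. The other tested probe of Spry4 differed by -0.01. The retinoid list had -0.04 (adjusted p = 0.556), with Crabp2 at -0.33, Aldh1a1 at 0.23 and Dhrs3 at 0.16. The extracellular matrix list had -0.08 (adjusted p = 0.134), with Col5a2 at -0.43, Postn at -0.44 and Lox at -0.31, and cartilage had -0.04 (adjusted p = 0.108), with Col11a2 at -0.41, Col9a3 at -0.32 and Chad at -0.34.

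Lists of other cells the pieces could hold were as follows. Exocrine pancreas had a median of -0.05 (adjusted p = 0.158), with Spink1 at 0.43, Cela1 at -0.32 and Cpb1 at -0.37. Endothelium had 0.16 (adjusted p = 0.0799), with Kdr at 0.16, Tie1 at 0.25 and Egfl7 at 0.12. Adipocytes had -0.18 (adjusted p = 0.551), with Cidec at 0.35, Fabp4 at -0.40 and Adipoq at -1.11 (SE 1.00). Immune cells had a median of 0.02 and a mean of -0.01 (adjusted p = 0.924), with Lck at -0.08, Cd79b at -0.06 and Tyrobp at 0.06. Lck had no value in wildtype replicate 1 and was -0.02 with scan batch as a block. Erythroid cells had 0.04 (adjusted p = 0.83), with Alas2 at -0.34 and Klf1 at 0.16, and mesothelium had -0.05 (adjusted p = 0.803), with Wt1 at 0.16, Msln at -0.15 and Upk3b at -0.06. Msln and Upk3b were near background on 3 arrays each and Klf1 on 1. The immediate early and heat shock list had 0.04 (adjusted p = 0.556), with Ier2 at -0.19, Hspa1b at 0.49 and Hspa1a at 0.41. Of the pancreatic islet list 4 genes were measured, too few for the set test. They included Ppy at -0.32 and Nkx6-1 at -0.50, the latter near background on 1 array.

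Several of these lists were called once arrays were left out or another setting was used. Each fit without 1 array, here and above, leaves the scan batches unequal between the labels and has no block, so scan batch enters its differences. Within batch B the mesenchyme regulators were lower by a median of -0.16 (adjusted p = 0.00592) and the extracellular matrix list by -0.21 (adjusted p = 0.00927). The mesenchyme list was also lower without wildtype replicate 1 (adjusted p = 0.0243) and with both kinds of array weights (0.0335 and 0.0126), as was the matrix list with the weights (0.0167 and 0.0126) and smooth muscle with the default ones (0.0341). Parietal and chief cells were higher without wildtype replicate 3 (adjusted p = 2.27e-05) or pair 3 (8.54e-10). Exocrine pancreas was lower without knockout replicate 1 (adjusted p = 0.000968), wildtype replicate 2 (0.00345) or wildtype replicate 3 (0.0391). That list scored 0.325 and 0.278 in the arrays of batch A and -0.348 to -0.258 in batch B. Each of these omissions moves its difference down through this gap alone. Batch A is pair 1, so the scan batch cannot be told apart from the litter or from the content of its pieces. Adipocytes were lower without knockout replicate 3 (adjusted p = 0.000822) or pair 3 (3.48e-08), enteric neurons and glia without knockout replicate 2 (0.0441), and FGF signalling without pair 2 (0.0328). Endothelium was higher without knockout replicate 3 (adjusted p = 0.0434) or with no filter on dim probes (0.0475), and cartilage was lower with the mean of probes per gene (0.0251). The direction of the test differed from that of the median for the Hox genes, tested as lower, and from that of the mean for Hedgehog signalling, tested as lower, and immune cells, tested as higher.

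The sex of the embryos is not given in the labels, and the arrays differed in it. Xist, the transcript of the inactive X chromosome, read 9.79 in wildtype replicate 1, 11.38 in knockout replicate 3 and 11.15 in wildtype replicate 3, and 6.04 to 6.46 on the other 3 arrays. The Y-linked gene Eif2s3y read 8.83, 9.91 and 9.54 in knockout replicate 1, knockout replicate 2 and wildtype replicate 2, and 6.42 to 6.59 on the rest. Ddx3y split the arrays the same way, with 6.93 to 7.64 against 5.74 to 5.90. Uty and Kdm5d did not separate the arrays, at 6.10 to 7.05 and 8.42 to 8.86, nor did another Xist probe, at 6.34 to 6.59.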

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

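The gene by gene array weights were chosen after seeing the data; all other settings were planned. The count of 0 genes held under all of them except the default array weights (677 genes, 462 higher and 215 lower), whose estimate stopped before it converged. Genes at an unadjusted p under 0.05, 189 as reported, numbered 760 with the litter pair as replicate block, 978 with scan batch as a block, 3823 with array weights, 1795 with gene by gene array weights, and 25 to 1918 when arrays or pairs were left out, the lowest without pair 3 and the highest without pair 1. The lists called, 5 as reported, were 3 with plain background subtraction and a floor, which lost liver (adjusted p = 0.0539) and cell cycle (0.0555), and 0 with an estimated correlation or fry. They were 4 with median scaling and both forms of the authors' values, 6 with no filter on dim probes, the mean of probes or gene by gene array weights, 7 with array weights, and 4 to 6 over left-out arrays or pairs. The replicate block kept these 5 lists. The intestinal and skeletal muscle lists were called in the same direction under all 25 settings of camera with the preset correlation, at adjusted p of at most 0.0015 and 0.0104. All these settings share that preset, so they do not address how far the members vary together. The robust trended prior, counted among the 25, does not enter camera and so repeats the main result for every list. The gastric list was lost in 4 of 25 and the cell cycle list in 10, among them median scaling (adjusted p = 0.0882) and both forms of the authors' values (0.114). The liver list reversed to -0.35 with array weights, -0.29 with gene by gene array weights and -0.38 to 1.16 over left-out arrays or pairs.

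Nkx3-2 reversed to -0.11 with array weights, -0.0177 with gene by gene array weights, and ranged from -0.0239 to 0.264 over left-out arrays. Of the other 94 named genes 77 kept their sign under every setting. Lck was 0.0745 with median scaling, 0.0329 with the authors' per-sample intensities and 0.0324 with the series matrix values, and Gli1 was -0.051 with only masked spots missing. With array weights the values were Gli1 -0.0199, Cpb1 0.0268, Tyrobp -0.0478, Fga -0.39 and Wt1 -0.19. With gene by gene array weights they were Cpb1 0.0269, Tyrobp -0.11, Fga -0.27 and Wt1 -0.11. Over left-out arrays or pairs the ranges were Cd79b -0.25 to 0.0659, Tyrobp -0.19 to 0.27, Fga -0.39 to 1.16, Cpb1 -0.70 to 0.15, Msln -0.34 to 0.0448, Upk3b -0.14 to 0.0409, Hspa1b -0.20 to 1.14, Hspa1a -0.30 to 1.05, Wt1 -0.0343 to 0.43, Synpo2 -0.27 to 0.00016, Dkk3 -0.68 to 0.0589, Adipoq -2.16 to 0.14, Kcnq1 -0.29 to 0.020, Cela1 -0.68 to 0.0186 and Nkx6-1 -1.35 to 0.0201. The arrays with high Xist, 3 as reported, were 1 to 3 among those kept. The causes were not tested, except that fewer arrays were used where some were left out. Scan batch together with the litter pair was not run, because each pair lies within 1 batch. Dim genes are limited by background, which the floor of the normexp offset draws towards 0 difference.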

Other observations

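All tests of explanations below were chosen after the result was seen, except the count of other splits for the number of genes. Some pancreatic genes stood above the other 4 arrays in both arrays of pair 1, namely 9 of the 17 members of the exocrine list, with Amy2a5 at 12.35 and 12.52 against 6.01 to 7.19, Cpa1 at 10.05 and 10.61 against 6.99 to 7.54, and Cela3b at 9.66 and 11.36 against 6.24 to 6.74. The other 8 did not, among them Cela1 at 9.77 and 9.38 against 8.96 to 9.98 and Cpb1 at 7.74 and 9.13 against 7.55 to 7.84. Atp4a and Cblif were higher in the array labelled knockout in pairs 1 and 2 and lower in pair 3. Atp4a, a proton pump subunit, read 11.69, 12.53 and 10.91 in knockout replicates 1 to 3 and 9.06, 11.29 and 13.02 in wildtype replicates 1 to 3, and Cblif, the gastric intrinsic factor gene, read 9.33, 10.36 and 9.28 against 7.02, 9.01 and 10.63. Atp4b, Pga5 and Aqp4 of the same list had these signs too, Hdc and Chia1 had no value in pair 3, and the others differed, with Slc26a7 at -0.17, 0.17 and 0.82 and Kcnq1 at -0.05, 0.09 and -0.54 in pairs 1 to 3. The fat cell gene Adipoq was lowest in knockout replicate 2, at 6.18, and highest in wildtype replicate 2, at 9.79. These genes were picked after their values were seen.

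The first pattern is the lower Tff2, Muc6 and Gkn3 in the arrays labelled knockout, the members of the gastric list with the largest t-statistics. Less gastric epithelium of every kind is argued against as the whole cause in pairs 1 and 2, if it shifts all members alike. In each pair left out, the 3 unsaturated members lowest in the other 2 pairs were compared with the other 10. These 3, always Tff2 and Muc6 with Gkn3 or Pgc, lay lower by more than the SD of those 10 in 3 of 3 pairs. The medians were -2, -1.27 and -0.96 against -0.04, 0.23 and -0.44. In pairs 1 and 2, 5 and 4 of the 10 others were lower. In pair 3 the others were lower too in 9 of 10, so less gastric epithelium stays open there. The pattern itself was picked over all 3 pairs. Pieces taken further towards the intestine, with less antrum, stay open: the intestinal list was higher in pairs 2 and 3, but in pair 1, where Tff2 and Muc6 were lowest, its median was -0.159, and 1 pair cannot decide. A change in the mucous gland cells of the antrum that follows the genotype may also account for it and was not tested separately.

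The second pattern is the higher intestinal epithelium list. Each scan batch holds as many arrays of either label. More intestine and less stomach wall in the pieces labelled knockout stays open: the intestinal list was higher and the list of stomach and pyloric mesenchyme regulators lower in the array labelled knockout in 2 of 3 pairs, and pair 1 had both signs turned. An effect of the genotype on the intestinal epithelium stays open too and was not tested separately. Pair 1 counts against either as a cause that acts the same way in all 3 pairs, and batch A holds no other pair. There the intestinal list (-0.16) and the mesenchyme list (0.11) turned sign together. The share of intestine can differ from piece to piece, so pair 1 does not weigh on both equally, and 1 pair cannot decide. By Xist and Eif2s3y the embryos of pair 1 also differed in sex, unlike those of pairs 2 and 3. A part of sex in the turned signs was not tested.

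The third pattern is the higher liver list. Higher liver genes in every knockout are argued against by its median of -0.211 without knockout replicate 1. Liver tissue in the piece of knockout replicate 1 is a candidate explanation: there 7 of 10 members were over 1 log2 unit higher than in wildtype replicate 1, with Alb at 12.75 against 7.60 and Fgb at 11.91 against 8.59. This stayed under the share of 0.8 set for the test, and the others were Ambp, Trf and Ttr, so it is left open. All 10 members were also measured above background on all 5 other arrays, so their signal is not confined to that array. Which cells give it there was not tested.

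The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 0 genes at an adjusted p under 0.05, as did the highest of the others, and all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 189 genes and the highest other 3945, with 7 splits at least as high as the real count. That highest split set both arrays of pair 1 with knockout replicate 2 against the rest, so it follows the scan batch and points to a structure of the samples. Among splits that part all 3 pairs, as the real one does, the highest other gave 288 genes. For lists called by camera the real split gave 5 and the highest other 5, with 4 splits at 5, of which 1 other parts all pairs.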
